A study of Homo sapiens with 18 samples.

How the data were processed

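RNA-seq gene counts were analysed for 8 libraries of HEK293 cells, 2 for each of 4 siRNA groups. The series also holds 10 H3K36me3 ChIP-seq samples, which were not analysed here. The files hold whole-number counts per gene, deposited by the authors without normalization. Per the submitters' processing notes, the tools named were FastQC, cutadapt, TopHat2 with Bowtie, HTSeq and DESeq, with TopHat2 version 2.0.10, R 3.2.2 and SAMtools named for set 2, and the genome build hg19. The gene annotation and the strand setting of the counting are not given in the sources used here, so no coordinates are printed, and antisense or overlapping genes cannot be told apart. Gene neighbours were looked up in RefSeq genes of GRCh38 by symbol. Each file lists 25369 gene symbols and 5 summary rows, which were left out of library totals and tests. Reads assigned to no gene made up 8.69 to 12.4 percent of the counted total, ambiguous reads 2.76 to 3.36 percent, and reads with more than 1 alignment 11.2 to 12.6 percent.

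Groups come from the sample titles. Libraries without a replicate number in the title (set 1, labelled total RNA) and those titled as replicate 2 (set 2, labelled polyA RNA) also differ in their extraction text and processing notes. Each group has 1 library in each set, so library set was a term of the model beside the 4 groups, as fixed before the data were examined. The deviations of the libraries from their group means correlated between groups at 0.724 to 0.794 across genes, and the first principal component of log2 CPM, with 56.2 percent of the variance, separated the sets. The labels do not say that the 2 libraries of a group come from separate cultures, so p-values measure only the spread between these libraries. The 10 most abundant genes took 4.54 to 6.20 percent of gene counts. The median standard error of a log2 fold change against NC was 0.12 over tested genes.

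Counts were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation and glmQLFTest, two-sided), after filterByExpr with a count minimum of 10 and TMM scaling; 16786 genes were tested, with 3 residual degrees of freedom. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. The 6 contrasts were taken from 1 fit. Standard errors are the log2 fold change divided by the square root of the F statistic. CPM values are TMM-scaled, computed here from the deposited counts, and group values are means ± SD of 2 libraries. Log2 ratios within a set used a prior count of 2. Of the lists, 26 fixed before the data were examined had at least 5 tested members, 625 genes in all, of which 10 stand in more than 1 list. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and with an estimated correlation, adjusted over the 78 tests of all lists in the 3 comparisons with NC, over the lists of the other 3 comparisons together, and over the lists of the added siSPOP against siSETD2 contrast alone. With an estimated correlation camera uses the 3 residual degrees of freedom of the fit. Few lists could pass it, so a failure there does not show by itself that a list was unchanged.

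Named genes follow a rule fixed before the data were examined. For each comparison with NC it takes SPOP, SETD2 and up to 10 genes with the largest positive and 10 with the largest negative log2 fold change among genes past the threshold with a mean of at least 5 CPM and the same sign in both sets. It leaves out uncharacterised loci, small RNAs and antisense genes. For the other comparisons it takes up to 5 in each direction, and in each list up to 4 tested members with the smallest p. Some of these were left out of the text for length, the results of some genes are not reported here, and any gene outside the rule is named in the text as chosen after its values were seen. On simulated counts for siSPOP against NC over 16786 genes, of which 100 were changed 1.5-fold and 100 2-fold, besides a list of 30 shifted genes, the edgeR step recovered 53 of 100 genes changed 1.5-fold and 81 of 100 changed 2-fold, with 11 false calls among 150, and camera at the preset correlation called 0 of 20 random lists. The simulated genes were drawn independently, so this does not test camera on lists whose members vary together. The p53 targets, for example, had an estimated correlation of 0.75. The alternatives tried were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, other filters on low counts, no term for library set, only the groups compared, counts thinned to the smallest library, and each library left out in turn; the closing section gives their effect. The simulations of unchanged groups drew negative binomial counts from the NC means of each set. GC content and gene length were not checked, because no hg19 annotation was used here.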

Results

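RNA was sequenced from HEK293 cells, an established human embryonic kidney line, transfected with siRNA, short RNAs that lower the level of a chosen transcript. The 8 RNA-seq libraries form 4 groups of 2: a negative-control siRNA (NC), an siRNA to SPOP (siSPOP), an siRNA to SETD2 (siSETD2) and both together (siDouble). SPOP is the substrate-binding part of a CUL3 ubiquitin ligase, and SETD2 is the enzyme that trimethylates lysine 36 of histone H3 (H3K36me3). The series asks how loss of the ligase acts on SETD2 and on splicing tied to H3K36me3; gene counts measure RNA level, not splicing or protein. Each group has 1 library in each of 2 sets that the labels describe differently, set 1 as total RNA and set 2 as polyA RNA. Reads counted to genes were 12124521, 10273894, 9136379 and 9929939 in set 1 (NC, siSPOP, siSETD2 and siDouble, each replicate 1). In set 2 they were 62550555, 71533448, 57823531 and 53599962 in the same order (replicate 2).

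The targeted transcripts were measured in every library first. SPOP stood at 56.2 and 62.0 CPM (counts scaled to the size of the library) in the NC libraries of sets 1 and 2. It was at 14.0 and 21.6 CPM in siSPOP, 55.5 and 55.2 in siSETD2, and 29.4 and 21.5 in siDouble. SETD2 stood at 79.8 and 65.4 CPM in NC, 70.4 and 64.2 in siSPOP, 33.8 and 32.3 in siSETD2, and 38.1 and 47.0 in siDouble. On the log2 scale SPOP changed by -1.65 ± 0.20 (SE) in siSPOP against NC, with edgeR adjusted p = 5.20e-04. In siDouble against NC it changed by -1.28 ± 0.20 (adjusted p = 0.00277), a call lost without NC replicate 1 (-1.33) or without NC replicate 2 (-1.18). SETD2 changed by -1.12 ± 0.11 in siSETD2 (adjusted p = 6.82e-07) and by -0.72 ± 0.10 in siDouble (adjusted p = 3.13e-05). SETD2 RNA in siSPOP was -0.10 ± 0.10 relative to NC, with adjusted p = 0.489. Its difference between siDouble and siSETD2 was 0.40 ± 0.11 (adjusted p = 0.0182), so the combined treatment left more SETD2 RNA than SETD2 siRNA alone. In set 2, siDouble kept 71.9 percent of the SETD2 of its NC library, and in set 1 47.7 percent. It kept 52.4 percent of SPOP in set 1 and 34.6 percent in set 2.

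**Figure D1:**
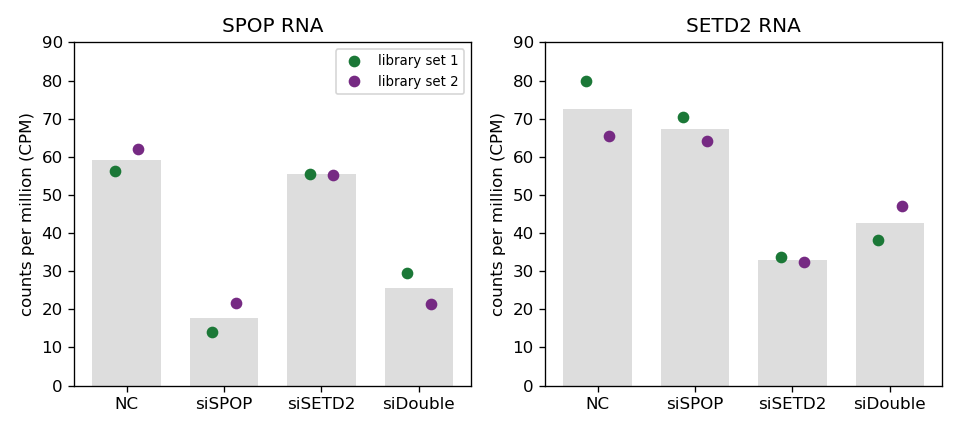
SPOP and SETD2 RNA in CPM (vertical axes) in each of the 8 libraries, by siRNA group; points are single libraries coloured by library set and grey bars are the mean of the 2. SPOP was lowest in the siSPOP library of set 1, at 14.0 CPM, and SETD2 in the siSETD2 library of set 2, at 32.3 CPM.

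SPOP siRNA against NC addresses the effect of the SPOP siRNA alone. CGA, which encodes the alpha subunit shared by the glycoprotein hormones, rose 17.1-fold, from 1.35 ± 0.442 to 25.5 ± 3.22 CPM (SD, n = 2 in each group). TPM4, a tropomyosin of the actin cytoskeleton, rose 3.37-fold, from 130 ± 6.04 to 437 ± 7.60 CPM. The ETS transcription factors ETV5 and ETV4 rose by 1.83 ± 0.12 and 1.62 ± 0.11 on the log2 scale, and UBE2QL1, HABP4, the nuclear receptor NR4A3 and the neurotrophin receptor NGFR by 2.39 ± 0.18, 1.59 ± 0.11, 1.56 ± 0.21 and 1.54 ± 0.19. HMOX1, the inducible heme oxygenase, fell 4.09-fold, from 26.7 ± 4.40 to 6.49 ± 1.55 CPM. The stress cytokine GDF15 changed by -2.16 ± 0.22, with -2.23 in set 1 and -2.21 in set 2, and RINL, IL32, SNCG and SYTL1 by -3.19 ± 0.23, -2.50 ± 0.20, -2.39 ± 0.19 and -2.05 ± 0.15. The edgeR adjusted p of these genes lay between 4.85e-14 (TPM4) and 1.30e-05 (NGFR).

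Among the gene lists, the targets of p53 had the smallest camera p in siSPOP: of 24 tested members, 0 rose and 15 fell (adjusted over the list alone, 1 and 19). MDM2, a ubiquitin ligase, changed by -1.13 ± 0.08, TP53INP1 by -1.17 ± 0.13, ZMAT3 by -1.17 ± 0.13 and the ribonucleotide reductase subunit RRM2B by -0.97 ± 0.12. The list median was -0.52 in set 1 and -0.51 in set 2 (adjusted p = 2.23e-11 by camera, adjusted p = 0.613 with an estimated correlation). Immediate early genes, respond within minutes to growth factor signals: of 23 tested members, 12 rose and 2 fell (adjusted over the list alone, 12 and 2) (adjusted p = 4.10e-05 by camera, adjusted p = 0.540 with an estimated correlation). The phosphatases DUSP1 and DUSP6 changed by 0.97 ± 0.08 and 1.21 ± 0.14, NR4A1 by 0.87 ± 0.09 and KLF4 by 0.88 ± 0.12. In the interferon response list, of 26 tested members, 1 rose and 13 fell (adjusted over the list alone, 1 and 13) (adjusted p = 0.00581 by camera, adjusted p = 0.540 with an estimated correlation). IRF7 changed by -1.16 ± 0.16, PARP12 by -0.99 ± 0.14 and IFIT3 by -1.66 ± 0.29. In the keratin and epithelial list, of 13 tested members, 1 rose and 9 fell (adjusted over the list alone, 1 and 9) (adjusted p = 1.36e-04 by camera, adjusted p = 0.540 with an estimated correlation), led by KRT19 at -0.90 ± 0.08 and the laminin and integrin subunits LAMB3 and ITGB4 at -1.42 ± 0.19 and -1.49 ± 0.20. In the Hedgehog target list, with GLI1 at 1.06 ± 0.14 and HHIP at 0.91 ± 0.15, of 14 tested members, 6 rose and 2 fell (adjusted over the list alone, 6 and 2) (adjusted p = 0.0443 by camera, adjusted p = 0.540 with an estimated correlation). The Hedgehog targets lost this call without NC replicate 1 (adjusted p = 0.0922) or without siSPOP replicate 1 (adjusted p = 0.0643) or without siDouble replicate 2 (adjusted p = 0.0530). For fibroblast and matrix genes, with COL6A1 at -1.03 ± 0.08 and SPARC at -1.34 ± 0.16, of 12 tested members, 1 rose and 4 fell (adjusted over the list alone, 1 and 4) (adjusted p = 0.0443 by camera, adjusted p = 0.791 with an estimated correlation). The fibroblast and matrix genes lost this call without siDouble replicate 1 (adjusted p = 0.0561) or without NC replicate 2 (adjusted p = 0.332) or without siSPOP replicate 2 (adjusted p = 0.222) or without siDouble replicate 2 (adjusted p = 0.0516).

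Genes of the splicing machinery bear on the study's question. In siSPOP U2AF1 changed by 0.41 ± 0.07 and SNRPB2 by -0.51 ± 0.10. In the core spliceosome list, of 41 tested members, 12 rose and 2 fell (adjusted over the list alone, 12 and 2), with 27 not called (adjusted p = 0.0197 by camera, adjusted p = 0.923 with an estimated correlation). The core spliceosome lost this call without NC replicate 2 (adjusted p = 0.0713) or without siSPOP replicate 2 (adjusted p = 0.0992). Among cytosolic ribosomal protein genes, some of which share reads with processed pseudogenes and are uncertain singly, of 50 tested members, 0 rose and 14 fell (adjusted over the list alone, 0 and 8) (adjusted p = 0.0280 by camera, adjusted p = 0.923 with an estimated correlation). The cytosolic ribosomal proteins lost this call without siSPOP replicate 1 (adjusted p = 0.129) or without NC replicate 2 (adjusted p = 0.584) or without siSETD2 replicate 2 (adjusted p = 0.0953) or without siDouble replicate 2 (adjusted p = 0.0516). Of 56 SR and hnRNP splicing regulators 5 rose and 2 fell, with 49 not called (adjusted p = 0.411 by camera, adjusted p = 0.970 with an estimated correlation). Neither splicing list passed in siSETD2 or siDouble. The core spliceosome medians in sets 1 and 2 were 0.03 and 0.18 in siSPOP, against -0.07 and -0.06 in siSETD2. Those of the SR and hnRNP regulators were -0.04 and 0.08 in siSPOP, against -0.09 and -0.05 in siSETD2. The H3K36me3 reader ZMYND11 changed by -0.76 ± 0.11 in siSPOP, -0.95 ± 0.11 in siSETD2 and -0.89 ± 0.11 in siDouble. Of 29 listed SPOP substrates 4 rose and 5 fell at the RNA level (adjusted p = 0.991 by camera, adjusted p = 0.999 with an estimated correlation). By edgeR's quasi-likelihood test with library set as a term, 5238 of 16786 genes passed the threshold in siSPOP against NC, 2282 higher and 2956 lower, and 791 of them changed at least 2-fold. The larger side turned with a filter at a mean of 1 CPM, to 2651 higher and 2549 lower. With library set left out of the model no gene passed in any of the 6 comparisons by edgeR; 1334 then had an unadjusted p under 0.05 here. The count was 3333 without siSPOP replicate 1, 3033 without siSPOP replicate 2, 2276 without NC replicate 2.

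**Figure D2:**
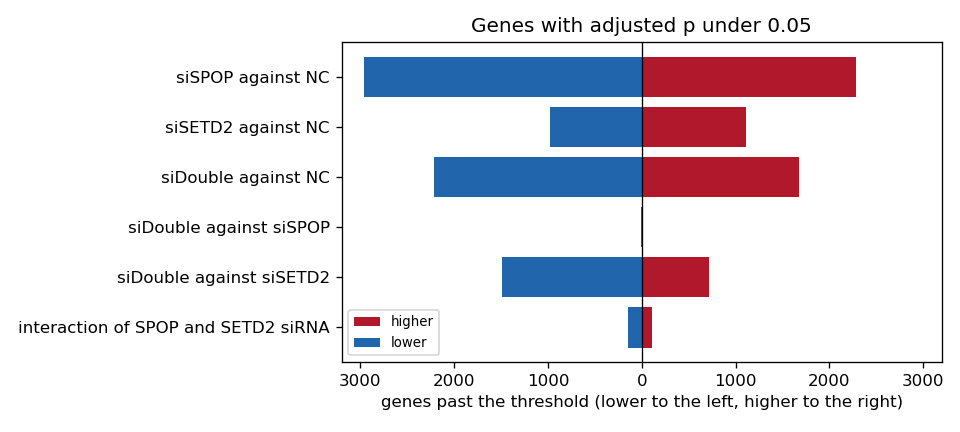
Genes past the edgeR threshold in the 6 comparisons, as a count of genes (horizontal axis), with those lower to the left in blue and those higher to the right in red. The longest bars are those of siSPOP against NC, with 2282 higher and 2956 lower, and siDouble against siSPOP has 15 genes in all.

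SETD2 siRNA against NC addresses the effect of the SETD2 siRNA alone. SETD2 has a single siRNA label here, so an off-target effect of this siRNA stays open and was not tested. TPM4 rose 2.87-fold, from 130 ± 6.04 to 373 ± 18.4 CPM (SD, n = 2). NGFR rose 3.51-fold to 17.9 ± 4.45 CPM, and CYP1B1, a cytochrome P450, 2.93-fold, from 10.9 ± 1.31 to 32.6 ± 6.31 CPM. The collagen COL23A1, the imprinted gene PHLDA2 and MAMLD1 rose by 1.52 ± 0.18, 1.64 ± 0.21 and 1.43 ± 0.16. SPRY4, a feedback inhibitor of receptor tyrosine kinase signalling, and the adhesion molecule L1CAM changed by 1.41 ± 0.22 and 1.51 ± 0.23, calls lost without siSETD2 replicate 2 (0.80 and 1.11). Besides SETD2 itself, TMBIM6, an endoplasmic reticulum membrane protein gene, fell by 1.03 ± 0.12 on the log2 scale, from 606 ± 26.1 to 297 ± 16.4 CPM. NME3, the glutathione-degrading CHAC1 and DNAAF3 changed by -1.05 ± 0.08, -1.11 ± 0.13 and -1.03 ± 0.12. The edgeR adjusted p of the genes named so far other than SPRY4 and L1CAM was at most 2.26e-04 (TMBIM6). EME2 also fell (-1.04 ± 0.12), but its gene overlaps MRPS34 in GRCh38 annotation and the counting rule for strand is not given, so reads of the pair cannot be told apart.

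Immediate early genes were the list with the smallest camera p in siSETD2: of 23 tested members, 15 rose and 0 fell (adjusted over the list alone, 17 and 0), with list medians of 0.64 in set 1 and 0.42 in set 2 (adjusted p = 3.57e-15 by camera, adjusted p = 0.540 with an estimated correlation). IER3 changed by 0.93 ± 0.12, KLF4 by 0.84 ± 0.13 and JUNB by 0.60 ± 0.10. For genes of the G1/S transition and DNA replication, of 30 tested members, 1 rose and 10 fell (adjusted over the list alone, 1 and 13) (adjusted p = 6.04e-05 by camera, adjusted p = 0.540 with an estimated correlation). The replicative helicase subunits MCM6 and MCM4 changed by -0.50 ± 0.08 and -0.45 ± 0.08, and UHRF1, which maintains DNA methylation, by -0.70 ± 0.10. In the hypoxia and glycolysis list, of 26 tested members, 1 rose and 11 fell (adjusted over the list alone, 1 and 12) (adjusted p = 4.83e-06 by camera, adjusted p = 0.540 with an estimated correlation), with LDHA at -0.53 ± 0.08 and PFKFB4 at -0.79 ± 0.13, which lost their calls without siSETD2 replicate 2 (-0.37 and -0.64). For cytosolic ribosomal protein genes, of 50 tested members, 0 rose and 13 fell (adjusted over the list alone, 0 and 19) (adjusted p = 7.42e-09 by camera, adjusted p = 0.760 with an estimated correlation). In the neural and kidney progenitor list, of 18 tested members, 4 rose and 0 fell (adjusted over the list alone, 6 and 0) (adjusted p = 3.87e-05 by camera, adjusted p = 0.540 with an estimated correlation), with NEFL at 0.78 ± 0.08 and SOX2 at 0.68 ± 0.09. The p53 target list, low in siSPOP, had a median of 0.25 in set 1 and 0.14 in set 2: of 24 tested members, 4 rose and 2 fell (adjusted over the list alone, 7 and 2) (adjusted p = 4.22e-04 by camera, adjusted p = 0.923 with an estimated correlation), with TP53I3 at 1.02 ± 0.17 (its call lost without siSETD2 replicate 2, 0.92). MDM2, which fell in siSPOP, was among the members that fell here too, a call lost without NC replicate 1 (-0.30). For Wnt and YAP targets, of 20 tested members, 4 rose and 0 fell (adjusted over the list alone, 9 and 0) (adjusted p = 0.00335 by camera, adjusted p = 0.540 with an estimated correlation), with AMOTL1 at 0.42 ± 0.08 (its call lost without siSETD2 replicate 2, 0.37). For Hedgehog targets, of 14 tested members, 5 rose and 0 fell (adjusted over the list alone, 6 and 1) (adjusted p = 0.00847 by camera, adjusted p = 0.540 with an estimated correlation). The Hedgehog targets lost this call without siSETD2 replicate 2 (adjusted p = 0.0702). For DNA repair genes, of 28 tested members, 0 rose and 3 fell (adjusted over the list alone, 0 and 7) (adjusted p = 7.35e-04 by camera, adjusted p = 0.680 with an estimated correlation). In all, 2088 genes passed by edgeR, 1110 higher and 978 lower, and 275 changed at least 2-fold. The larger side turned with no filter, to 1159 higher and 1253 lower, and with upper-quartile scaling, to 1049 and 1050. The count was 1144 without NC replicate 1, 1343 without NC replicate 2, 1055 without siSETD2 replicate 1, 420 without siSETD2 replicate 2. An edgeR fit to the siSETD2 and NC libraries alone called 3802.

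A direct contrast of siSPOP with siSETD2, added after the comparisons with NC had been seen, tested whether the p53 target list differed between them. Its median was -0.78 on the log2 scale, and 22 of 24 members were lower in siSPOP and 0 higher by edgeR (adjusted over the list alone, 23 and 0) (adjusted p = 4.24e-23 by camera, adjusted p = 0.751 with an estimated correlation). Other lists passed as well. Both splicing lists were higher in siSPOP: core spliceosome (median 0.15, adjusted p = 1.97e-04 by camera) and SR and hnRNP regulators (median 0.11, adjusted p = 0.0413 by camera). With an estimated correlation each had adjusted p = 0.751 by camera.

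**Figure D3:**
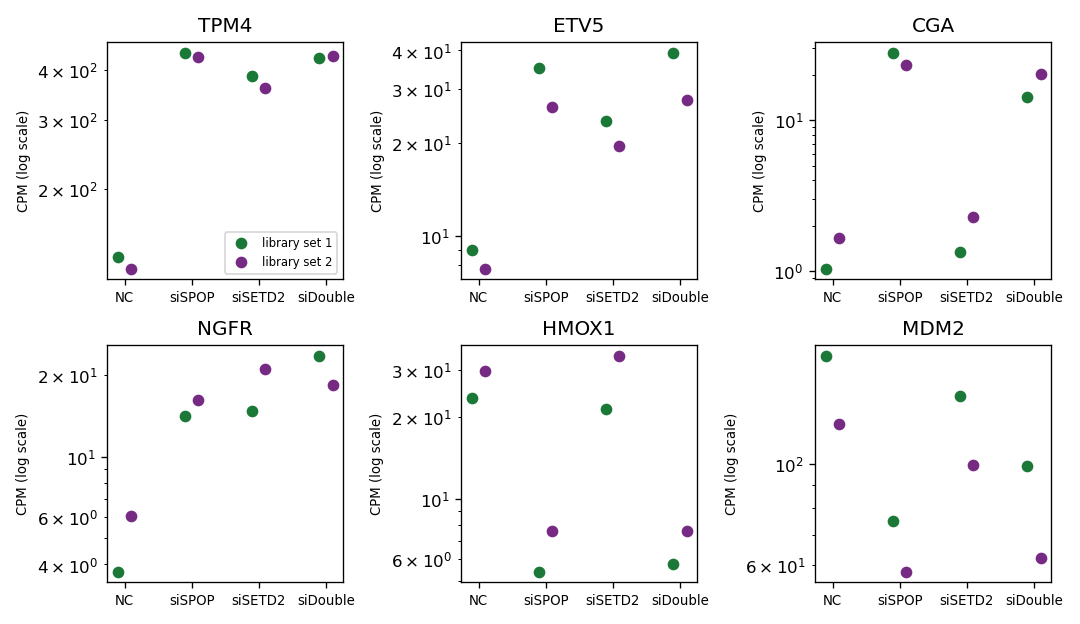
CPM on a log scale (vertical axes) of TPM4, ETV5, CGA, NGFR, HMOX1 and MDM2 in each library, by siRNA group and coloured by library set. TPM4 lies at 130 ± 6.04 CPM in NC against 437 ± 7.60, 373 ± 18.4 and 433 ± 4.57 (SD, n = 2) in siSPOP, siSETD2 and siDouble, and CGA lies at 1.81 ± 0.669 CPM in siSETD2 against 17.3 ± 4.24 in siDouble.

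The combined siRNAs against NC gave many of the changes of siSPOP. CGA rose by 3.58 ± 0.21 on the log2 scale to 17.3 ± 4.24 CPM (SD, n = 2), TPM4 3.34-fold to 433 ± 4.57 CPM, and ETV5, ETV4, NGFR and SPRY4 by 1.94 ± 0.12, 1.64 ± 0.11, 1.96 ± 0.19 and 1.71 ± 0.22 on the log2 scale. HMOX1 fell 4.00-fold to 6.70 ± 1.31 CPM, and RINL, IL32 and SYTL1 changed by -2.75 ± 0.23, -2.39 ± 0.20 and -2.12 ± 0.16. The edgeR adjusted p of these genes was at most 6.65e-06 (RINL). GDF15 changed by -1.78 ± 0.22, with -0.54 in set 1 and -2.06 in set 2; its call was lost without siDouble replicate 2 (-0.76).

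In the keratin and epithelial list, of 13 tested members, 1 rose and 9 fell (adjusted over the list alone, 2 and 10) (adjusted p = 4.31e-06 by camera, adjusted p = 0.540 with an estimated correlation), with KRT19 at -0.94 ± 0.08 and LAMB3 at -1.67 ± 0.20. For immediate early genes, of 23 tested members, 11 rose and 0 fell (adjusted over the list alone, 15 and 1) (adjusted p = 2.55e-09 by camera, adjusted p = 0.540 with an estimated correlation), with DUSP6 at 1.41 ± 0.14 and DUSP1 at 0.90 ± 0.08. In the interferon response list, of 26 tested members, 1 rose and 12 fell (adjusted over the list alone, 2 and 13) (adjusted p = 0.00668 by camera, adjusted p = 0.540 with an estimated correlation), with IRF7 at -1.17 ± 0.17. The interferon response lost this call without siDouble replicate 2 (adjusted p = 0.0671). For Hedgehog targets, of 14 tested members, 6 rose and 0 fell (adjusted over the list alone, 6 and 0) (adjusted p = 7.36e-04 by camera, adjusted p = 0.540 with an estimated correlation), with GLI1 at 0.90 ± 0.14 and CCND2 at 0.54 ± 0.07. Among neural and kidney progenitor genes, of 18 tested members, 6 rose and 0 fell (adjusted over the list alone, 7 and 0) (adjusted p = 0.00145 by camera, adjusted p = 0.540 with an estimated correlation), with SOX2 at 0.65 ± 0.10. In the integrated stress and unfolded protein response list, of 30 tested members, 0 rose and 8 fell (adjusted over the list alone, 1 and 8) (adjusted p = 0.00561 by camera, adjusted p = 0.725 with an estimated correlation), with CHAC1 at -1.36 ± 0.14 and SEL1L at -0.57 ± 0.09. Among cytosolic ribosomal protein genes, of 50 tested members, 0 rose and 10 fell (adjusted over the list alone, 0 and 10) (adjusted p = 0.00538 by camera, adjusted p = 0.923 with an estimated correlation). The cytosolic ribosomal proteins lost this call without NC replicate 2 (adjusted p = 0.426) or without siDouble replicate 2 (adjusted p = 0.153). The p53 target list differed between the sets in siDouble, with medians of 0.00 in set 1 and -0.48 in set 2: of 24 tested members, 0 rose and 8 fell (adjusted over the list alone, 0 and 10) (adjusted p = 7.55e-04 by camera, adjusted p = 0.923 with an estimated correlation). The camera call was lost without NC replicate 2 (adjusted p = 0.0609) or without siDouble replicate 2 (adjusted p = 0.809). In the hypoxia and glycolysis list, of 26 tested members, 1 rose and 14 fell (adjusted over the list alone, 2 and 15) (adjusted p = 0.00415 by camera, adjusted p = 0.605 with an estimated correlation). By edgeR 3886 genes passed, 1671 higher and 2215 lower, and 569 changed at least 2-fold. The larger side turned with a filter at a mean of 1 CPM, to 2026 higher and 1820 lower. The count was 1652 without NC replicate 2, 1985 without siDouble replicate 2. A fit to the siDouble and NC libraries alone called 2314.

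**Figure D4:**
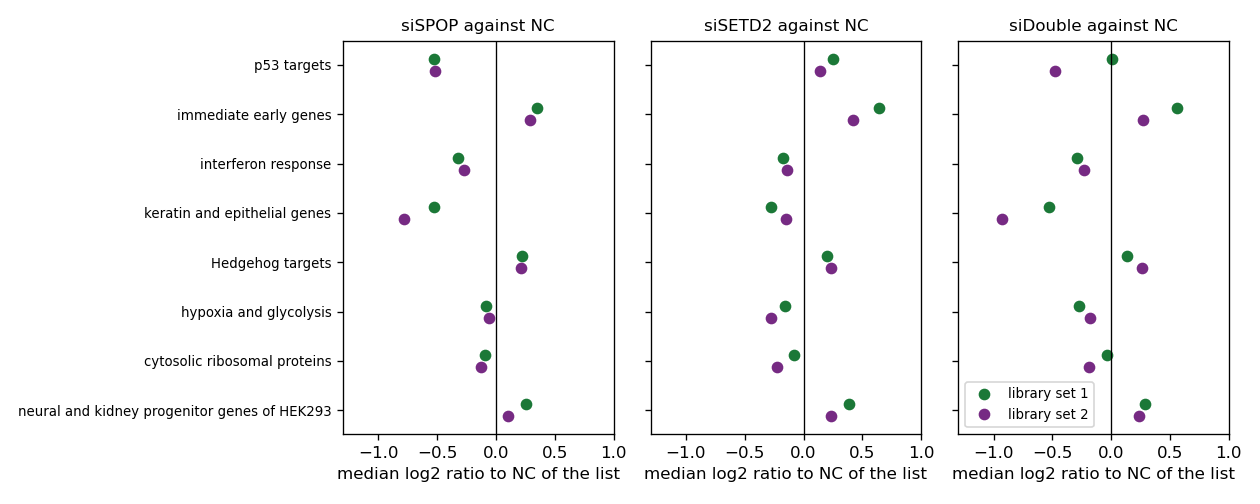
Median log2 ratio to the NC library of the same set (horizontal axis) over the members of 8 gene lists, for siSPOP, siSETD2 and siDouble; each point is 1 library set. The p53 target list lies at -0.52 in set 1 and -0.51 in set 2 for siSPOP, and at 0.00 in set 1 and -0.48 in set 2 for siDouble.

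Adding SETD2 siRNA to SPOP siRNA, siDouble against siSPOP, changed few genes by edgeR. SETD2 itself changed by -0.62 ± 0.10 (adjusted p = 0.0219). This call was lost without siSPOP replicate 1 (-0.58), without siSPOP replicate 2 (-0.68), without siDouble replicate 1 (-0.43) or with limma-voom (-0.58). SESN3, a sestrin, rose by 0.59 ± 0.09 (adjusted p = 0.0109), and TP53INP1 and ZMAT3, from the p53 target list, by 0.75 ± 0.14 and 0.73 ± 0.13 (adjusted p = 0.0275 and 0.0439). The amino acid transporter genes SLC43A2 and SLC6A9 changed by -0.63 ± 0.12 and -0.60 ± 0.11 (adjusted p = 0.0275 and 0.0283). Genes that rose lost their calls when a library was left out: SESN3 without siSPOP replicate 1 (0.49), TP53INP1 without siSPOP replicate 1 (0.58), without siDouble replicate 1 (0.61) and ZMAT3 without siSPOP replicate 1 (0.51). So did SLC43A2 without siSPOP replicate 1 (-0.65), without siDouble replicate 1 (-0.49), without siSPOP replicate 2 (-0.60) and SLC6A9 without siSPOP replicate 1 (-0.48), without siDouble replicate 1 (-0.45). In the p53 target list, of 24 tested members, 2 rose and 0 fell (adjusted over the list alone, 6 and 0), with medians of 0.59 in set 1 and 0.06 in set 2 (adjusted p = 3.32e-15 by camera, adjusted p = 0.853 with an estimated correlation). SPOP RNA did not pass between these groups (0.37 ± 0.21, edgeR adjusted p = 0.595), but its log2 ratios were 1.07 in set 1 and -0.01 in set 2. For this list and its members, the added SETD2 siRNA therefore cannot be told apart from weaker SPOP knockdown in siDouble replicate 1. For integrated stress and unfolded protein response genes, of 30 tested members, 0 rose and 0 fell (adjusted over the list alone, 0 and 8) (adjusted p = 2.35e-05 by camera, adjusted p = 0.853 with an estimated correlation). In total 15 genes passed, 11 higher and 4 lower, none of them by 2-fold. Here 1766 had an unadjusted p under 0.05, and DESeq2 called 68 and limma-voom 4. The count was 1250 without siDouble replicate 2, 108 without NC replicate 1, 67 without NC replicate 2, 25 without siSETD2 replicate 1, 5 without siDouble replicate 1, 1 without siSPOP replicate 1. Within set 2 the log2 ratios to NC of siDouble and siSPOP correlated across genes at 0.889, and within set 1 at 0.576. Those of siDouble and siSETD2 correlated at 0.468 in set 2 and at 0.604 in set 1. All these values contain the chance values of a shared NC library, and genes are not independent replicates.

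In siDouble against siSETD2, which adds SPOP siRNA to SETD2 siRNA, 2199 genes passed by edgeR, 714 higher and 1485 lower. SETD2 RNA was also higher in siDouble, by 0.40 ± 0.11 on the log2 scale (edgeR adjusted p = 0.0182). Its log2 ratios were 0.17 in set 1 and 0.54 in set 2. This contrast alone therefore cannot tell the added SPOP siRNA apart from weaker SETD2 knockdown in siDouble. DESeq2 called 1444, and edgeR on counts thinned to the smallest library 1276. CGA rose 8.78-fold, from 1.81 ± 0.669 to 17.3 ± 4.24 CPM (SD, n = 2). SLC43A2 and SCN8A, a neuronal sodium channel, rose by 0.96 ± 0.13 and 0.95 ± 0.14. GDF15, RINL, HMOX1 and DHRS2 changed by -2.69 ± 0.22, -2.57 ± 0.24, -2.06 ± 0.13 and -1.77 ± 0.20. The edgeR adjusted p of these genes lay between 5.31e-10 (HMOX1) and 9.88e-05 (SCN8A). In the p53 target list, of 24 tested members, 0 rose and 13 fell (adjusted over the list alone, 0 and 19), with medians of -0.34 in set 1 and -0.61 in set 2 (adjusted p = 5.19e-17 by camera, adjusted p = 0.853 with an estimated correlation). The count of genes was 1030 without siSETD2 replicate 1, 254 without siSETD2 replicate 2, 3650 without siDouble replicate 1, 259 without siDouble replicate 2.

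The single siRNAs shared part of their changes against NC. TPM4, HABP4, NGFR and ETV5 rose with each: HABP4, for example, stood at 14.9 ± 3.91 CPM in NC, 46.0 ± 3.75 in siSPOP and 40.5 ± 2.27 in siSETD2 (SD, n = 2). NME3 fell with each, by 1.23 ± 0.08 and 1.05 ± 0.08 on the log2 scale. By edgeR 477 genes were higher in both comparisons and 517 lower in both, and 117 were called in opposite directions. DESeq2 gave 378 higher and 335 lower in both. Independent lists of these sizes would share 151 and 172, and 20 simulations of unchanged groups against the same NC libraries shared at most 1 and 0. Log2 fold changes correlated across genes at 0.376, against a mean of 0.488 in the simulations; their covariance was 0.0835 against 0.0364. Part of the excess may come from the shared NC libraries, of which each set has 1, so they cannot be split within a set. A comparison across sets, which share no library, is given below. The siSPOP and siDouble comparisons shared 1313 higher and 1865 lower genes (227 and 390 for independent lists, at most 1 and 0 simulated), with a covariance of 0.224 against 0.0363. The siSETD2 and siDouble comparisons shared 608 and 618 (110 and 129 for independent lists, at most 2 and 1 simulated), with a covariance of 0.112 against 0.0358.

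The interaction asks whether the effect of SPOP siRNA differed with SETD2 siRNA present. It cannot tell such a difference apart from weaker knockdown of the targets in siDouble. SPOP and SETD2 themselves had interactions of 0.47 ± 0.28 and 0.50 ± 0.15, not past the threshold (edgeR adjusted p = 0.558 and 0.0990). TPM4 had the smallest adjusted p of the named interaction genes: its interaction on the log2 scale was -1.54 ± 0.10 (edgeR adjusted p = 1.29e-09), since each siRNA alone and both together gave about the same level, 437 ± 7.60, 373 ± 18.4 and 433 ± 4.57 CPM (SD, n = 2). UBE2QL1 and HABP4 had interactions of -1.74 ± 0.24 and -1.40 ± 0.15 (adjusted p = 2.57e-04 and 7.56e-06). ATP1B2, a sodium pump subunit, had 0.96 ± 0.17 (adjusted p = 0.00330). Its level was 31.6 ± 7.93 CPM in NC and 16.0 ± 8.03, 22.3 ± 8.45 and 20.3 ± 8.06 in siSPOP, siSETD2 and siDouble. The call was lost without siSPOP replicate 2 (0.73). Among immediate early genes, 0 had a positive and 3 a negative interaction of 23 (adjusted over the list alone, 0 and 10) (adjusted p = 2.14e-11 by camera, adjusted p = 0.853 with an estimated correlation). In all 253 genes passed, 107 with a positive and 146 with a negative interaction. The count was 141 without siSPOP replicate 1, 123 without siSPOP replicate 2, 129 without siSETD2 replicate 1, 56 without siSETD2 replicate 2, 556 without siDouble replicate 1, 694 without siDouble replicate 2. With limma-voom it was 126.

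The library sets, which share no library, were compared by the log2 ratio of each group to its own NC library over the 16786 tested genes. Pearson's r across genes was 0.577 for siSPOP, 0.467 for siSETD2 and 0.402 for siDouble, and Spearman's rho 0.626, 0.488 and 0.439. For genes with a mean of at least 10 CPM, Pearson's r was 0.85, 0.75 and 0.65. Genes are not independent replicates, so these values describe the libraries and carry no test. Of the genes called by edgeR, 99.4, 99.8 and 98.4 percent had the same sign in both sets in the siSPOP, siSETD2 and siDouble comparisons with NC, which is expected in part because the joint fit chose them on both sets.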

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

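The tests of a shared NC effect, of chance values of the NC libraries with their shuffled shares and of the SETD2 knockdown were chosen, or had their bounds reworded, after their results were seen, and only the test that leaves out siDouble replicate 1 was worded before. By edgeR estimates, both targets fell less in siDouble. SPOP changed by -1.65 in siSPOP against NC and by -1.18 in siDouble against siSETD2. SETD2 changed by -1.12 in siSETD2 against NC and by -0.62 in siDouble against siSPOP. The interaction term cannot tell this apart from an effect of 1 siRNA that depends on the other. By edgeR 253 genes passed for this term. The named ones were ITGB4 (1.34), CCPG1 (1.09), RAB26 (1.03), EME2 (1.00, which overlaps MRPS34), ATP1B2 (0.96), UBE2QL1 (-1.74), TPM4 (-1.54), HABP4 (-1.40), NGFR (-1.39) and EPHB1 (-1.28), as interactions on the log2 scale. Of the 253 genes, 230 were also called in the same direction by both single siRNAs, and in these 230 the interaction had the opposite sign. Calls were lost when a library was left out for ITGB4 without siSETD2 replicate 1 (1.19), without NC replicate 2 (1.10), without siSPOP replicate 2 (1.27) and EME2 without siSPOP replicate 2 (0.94). The same held for CCPG1 without NC replicate 1 (0.98), without siSPOP replicate 1 (1.07), without siSETD2 replicate 1 (0.93), without siSPOP replicate 2 (1.15), without siSETD2 replicate 2 (1.39). It held for RAB26 without siSPOP replicate 1 (0.90), without siSETD2 replicate 1 (0.97), without NC replicate 2 (1.11), without siSETD2 replicate 2 (1.20). The remaining ones were ATP1B2 without siSPOP replicate 2 (0.73), NGFR without siSPOP replicate 1 (-1.39), without siSPOP replicate 2 (-1.40), without siSETD2 replicate 2 (-1.13) and EPHB1 without siSPOP replicate 1 (-1.14), without siSETD2 replicate 2 (-1.49).

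Of the 253 interaction genes, 247 changed with the same sign under either siRNA. The NC level enters both single changes and, with the opposite sign, the interaction. Part of this count and of the 230 above is therefore built in. If NC alone stood apart, both siRNAs would give about the change of each single one, against a ratio of 2 for changes that add up, or less with the weaker knockdown in siDouble: in genes of at least 5 CPM changed the same way by both single siRNAs in 1 set, by at least 0.5 on the log2 scale, the ratio of the siDouble median to the mean of the single medians in the other set was 1.13 (331 genes chosen in set 1) and 1.12 (240 chosen in set 2), and from 1 on the log2 scale 1.03 (24) and 1.33 (13). The last lies outside the bound set for an NC effect, on few genes, so an effect of the NC siRNA cannot be told apart from a response that saturates with either knockdown or adds in part; this test replaced a ratio of 1.11 over the 994 genes called in both single comparisons, a choice of genes that draws the ratio toward 1. For chance values of the shared NC libraries, genes of at least 5 CPM with a log2 ratio of at least 1 in either direction in siSPOP of 1 set were compared with siSETD2 of the other set: 74.2 percent of 306 had the same sign from siSPOP of set 1, and 54.8 percent of 248 from siSPOP of set 2. With the siSETD2 ratios shuffled among genes of similar expression the median share was 51.0 and 49.2 percent (95 percent of shuffles 45.4 to 56.5 and 43.1 to 55.2), so only the first pairing lay beyond them. These genes were taken by their siSPOP change alone, shared with siSETD2 or not. The shares therefore cannot decide on the shared changes, and this test leaves the explanation open. Simulated unchanged groups shared at most 1 and 0 calls against 477 and 517, with a covariance of at most 0.0410 against 0.0835, but take their spread from the fit and decide nothing alone. The genes changed the same way by at least 0.5 in 1 set had medians in the other set of 0.63 (siSPOP) and 0.54 (siSETD2) over 331 genes. Over the 240 they were 0.76 and 0.62. Chance values of NC would not carry over to a set with another NC library, so these medians argue against them as the main cause for these genes. An effect of the NC siRNA and a shared response to both knockdowns may each contribute, and chance values of NC may add a part.

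The small number of genes in siDouble against siSPOP, 15, stood beside 2088 in siSETD2 against NC. A weaker SETD2 knockdown in siDouble would give a steeper slope in the set with the stronger fall. Over the 2088 genes called in siSETD2 against NC, the slope of the siDouble to siSPOP change on the siSETD2 to NC change was 0.17 in the joint fit, 0.37 in set 1 and 0.11 in set 2, against SETD2 ratios of 0.55, 0.72 and 0.44. Over the 977 of them not called in siSPOP the slopes were 0.32, 0.53 and 0.17, so the distance from a proportional effect depends on the genes taken. The order is what the explanation needs, but the joint slope was to lie within 2 standard errors of the SETD2 ratio (SE 0.11) and did not with either choice of genes, so a weaker knockdown as a part of the cause cannot be told apart with 1 library per set. Genes chosen by their siSETD2 call overstate that change, which lowers the slope whatever the cause. SPOP in siDouble against siSPOP was 1.07 in set 1 and -0.01 in set 2, so the order of the slopes also follows SPOP. Without siDouble replicate 1 the count was 5, but without siDouble replicate 2 it was 1250: the low count rests on siDouble replicate 2. By its wording the test ruled out a difference between the siDouble libraries; that reading was dropped after the 1250 was seen, because the test had looked at the other library.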

How the results depend on the processing

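The contrast of siSPOP with siSETD2 on the lists and the shuffled shares and held-out ratios across sets were added after results had been seen, and the other alternatives were fixed before. Scaling by RLE or upper quartile, a filter at a mean of 1 CPM, DESeq2 and limma-voom kept the counts of siSPOP, siSETD2 and siDouble against NC within 1.5 times, and moved the share of higher calls by under 10 percentage points in the 5 comparisons other than siDouble against siSPOP. The larger side turned even so. In siSPOP it was 2651 higher and 2549 lower with the 1 CPM filter, 3267 higher and 3083 lower without siDouble replicate 2 and 2399 higher and 2351 lower without siSETD2 replicate 2. In siDouble it was 2026 higher and 1820 lower with that filter, 1463 higher and 1299 lower with counts thinned, 1065 higher and 920 lower without siDouble replicate 2, 1730 higher and 1607 lower without siSETD2 replicate 2 and 1943 higher and 1778 lower without siSPOP replicate 2. In siSETD2 it was 1159 higher and 1253 lower with no filter and 1049 higher and 1050 lower with upper-quartile scaling. With no term for library set (no block) edgeR called 0 genes in each of the 6 comparisons, with 1334, 510, 847, 53, 421, 97 at an unadjusted p under 0.05 in the order of the report, and 0 shared calls. The target changes without the block lost their calls: SPOP -1.72 in siSPOP and -1.22 in siDouble against NC, SETD2 -1.13 in siSETD2 and -0.77 in siDouble against NC, and -0.66 in siDouble against siSPOP. Lists past the threshold without the block numbered 4 in siSPOP and 6 in siDouble, against 8 and 10. With an estimated correlation the number was 0 in each comparison with NC, and the lowest adjusted p was 0.540.

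In siDouble against siSPOP the count was 5 with upper-quartile scaling, 68 with DESeq2, 4 with limma-voom, 120 with no filter, 66 with counts thinned and 216 with only these groups; the SETD2 change there was -0.58 with limma-voom, no longer past the threshold. In siDouble against siSETD2 it was 1444 with DESeq2 and 1276 with counts thinned. The interaction count was 126 with limma-voom and 472 with no filter. With only the groups compared, siSETD2 against NC had 3802 and siDouble against NC 2314. DESeq2 gave 335 genes lower in both single comparisons. Set agreement over genes of at least 10 CPM was 0.85, 0.75 and 0.65. PDGFRB in siSPOP had 0.18 in set 1 alone, against -1.51 ± 0.46 in the joint fit; its call was lost for PDGFRB without NC replicate 2 (-0.55), without siSPOP replicate 2 (-0.04). Leaving out 1 library gave ranges of 2276 to 6350 genes (siSPOP), 420 to 3077 (siSETD2) and 1652 to 4321 (siDouble) against NC. For the other comparisons they were 1 to 1250 (siDouble against siSPOP), 254 to 3650 (siDouble against siSETD2) and 56 to 694 (interaction). For SPOP the ranges were -2.11 to -1.42 and -1.55 to -0.87 in siSPOP and siDouble. For SETD2 they were -1.29 to -0.98, -0.98 to -0.53 and -0.92 to -0.43 in siSETD2, siDouble and siDouble against siSPOP. The number of lists was 5 to 8, 9 to 13 and 9 to 11 in siSPOP, siSETD2 and siDouble. A group left with 1 library was assumed to vary like the others. The cause of these shifts was not tested. Of 360 named gene results, 3 lost their call with RLE, 14 of 357 with DESeq2, 24 with limma-voom and 30 of 358 with counts thinned to the smallest library. With no block all 360 lost it, 92 without NC replicate 2, 75 without siSETD2 replicate 2, 51 without NC replicate 1, 43 without siSETD2 replicate 1, 40 without siSPOP replicate 2, 38 without siSPOP replicate 1, 30 without siDouble replicate 2 and 14 without siDouble replicate 1. None reversed under these. List calls outside the comparisons with NC, PHLDA1, DUSP4, SPRY2, EPHA2 and EPHA4 were not refitted this way.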

Other observations

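The test of ERK output, the genes DUSP4, SPRY2, CCND1, PHLDA1, EPHA2 and EPHA4 and the contrast of siSPOP with siSETD2 were chosen after results had been seen. Among nuclear-retained RNAs in siDouble, of 11 tested members, 3 rose and 0 fell (adjusted over the list alone, 3 and 0) (adjusted p = 0.0434 by camera, adjusted p = 0.540 with an estimated correlation). The nuclear-retained RNAs lost this call without NC replicate 1 (adjusted p = 0.113) or without siDouble replicate 1 (adjusted p = 0.137). NEAT1, which scaffolds paraspeckles, changed by 0.48 ± 0.07 in siSPOP, 0.66 ± 0.07 in siSETD2 and 0.46 ± 0.07 in siDouble, and MALAT1 by 0.47 ± 0.08 in siDouble. INSIG1, a brake on cholesterol synthesis, rose by 0.69 ± 0.08, 0.58 ± 0.08 and 0.78 ± 0.08 in the same order of groups, while MSMO1, an enzyme of that pathway, changed by -0.43 ± 0.10, -0.65 ± 0.10 and -0.52 ± 0.10, its siSETD2 call lost without siSETD2 replicate 2 (-0.51). The respiratory complex III subunit UQCRFS1 changed by -0.62 ± 0.10 in siDouble, against SDHB at 0.48 ± 0.07. HSPA1A and HSPA1B, near-identical copies whose counts are uncertain singly, changed by -0.53 ± 0.09 and -0.62 ± 0.10 in siSPOP. The remaining lists passed in no comparison with NC: adjusted p by camera at the preset correlation for siSPOP, siSETD2 and siDouble was 0.574, 0.206, 0.573 for H3K36 methylation enzymes, 0.193, 0.504, 0.753 for H3K36me3 readers and 0.247, 0.991, 0.448 for cullin-RING ligase parts. It was 0.427, 0.0702, 0.427 for G2/M genes and 0.351, 0.983, 0.998 for heat shock proteins. For cholesterol synthesis it was 0.874, 0.427, 0.302. It was 0.0743, 0.970, 0.138 for the respiratory chain, 0.293, 0.947, 0.455 for histones and 0.753, 0.991, 0.753 for blood cell genes.

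The p53 target list was lower in siSPOP than in NC. Whether 1 library set alone carried this fall was checked in a way chosen before the set values were seen. The list median was -0.52 in set 1 and -0.51 in set 2, each below all of 10000 random lists matched on expression. The fall was therefore present in both sets. Each ratio is taken within a set, so a difference in level between the sets was removed beforehand. The list already had the smallest camera p in siSPOP in these same libraries. Low set medians were therefore likely and give no independent support. Random lists ignore the correlation between members, and with an estimated correlation the list did not pass in siSPOP (adjusted p = 0.613 by camera). In siDouble the median lay at percentile 69.0 of the random lists in set 1, where siDouble kept 52.4 percent of SPOP, and below all of them in set 2, where it kept 34.6 percent. SETD2 differed between these libraries as well, with 47.7 percent kept in set 1 and 71.9 percent in set 2. SETD2 siRNA alone gave list medians of 0.25 in set 1 and 0.14 in set 2. With 1 library per set, the levels of SPOP and SETD2 cannot be told apart here. Each target has a single siRNA label here, so an off-target effect of either siRNA stays open and was not tested.

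ETV4 and ETV5 are known outputs of the ERK kinase pathway and were higher in all 3 siRNA groups. As a hypothesis, ERK output may be higher than in NC. It was tested on 8 other ERK output genes, chosen after ETV4 and ETV5, and perhaps some of their own values, had been seen. The 8 include SPRY4 and DUSP6, which are among the genes named above as changed. The percentiles are therefore in part built in and give no independent support. The median log2 fold change of the 8 genes was 0.20 in siSPOP, 0.63 in siSETD2 and 0.43 in siDouble, at percentiles 96.35, 100 and 99.99 of matched random lists. The lowest, in siSPOP, stayed between the bounds of the test, so the test leaves the hypothesis open. Of the 8 genes 4 rose and 1 fell in siSPOP, 6 and 0 in siSETD2, and 5 and 0 in siDouble. PHLDA1, EPHA2 and EPHA4 changed by -0.25 ± 0.16, 0.00 ± 0.13 and 0.01 ± 0.10 in siSPOP, by 0.23 ± 0.16, 0.76 ± 0.12 and 0.27 ± 0.10 in siSETD2 and by -0.04 ± 0.16, 0.34 ± 0.13 and 0.29 ± 0.10 in siDouble. DUSP4 changed by 1.20 ± 0.12, 1.07 ± 0.12 and 1.33 ± 0.12 in siSPOP, siSETD2 and siDouble, SPRY2 by 0.40 ± 0.12, 0.50 ± 0.12 and 0.53 ± 0.12, and CCND1 by -0.33 ± 0.08, 0.29 ± 0.08 and 0.02 ± 0.08. The siSPOP call was lost for CCND1 without siSPOP replicate 1 (-0.24), without NC replicate 2 (-0.30), and the siSETD2 call for CCND1 without NC replicate 1 (0.29), without siSETD2 replicate 1 (0.33), without NC replicate 2 (0.30), without siSETD2 replicate 2 (0.26).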
